A study of Mus musculus with 12 samples.

How the data were processed

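Islets from Gpr31b knockout and wild-type mice were measured by RNA sequencing after 24 h with vehicle or with TNF-α, IFN-γ and IL-1β, in 12 libraries, 3 in each of 4 groups. Per the labels' protocols, polyadenylated RNA was made into strand-specific libraries and sequenced on an Illumina NovaSeq instrument. The values are raw counts per gene as the authors deposited them, in 1 table of the 6 vehicle libraries and 1 table of the 6 cytokine libraries, with the same 24552 gene symbols in the same order. Per the submitters' processing notes, Trimmomatic, FastQC, HTSeq and DESeq2 were used and the genome build was mm10 (GRCm38); their versions and roles, the aligner, the annotation and the strand setting of the counting are not given in the sources used here. Column names give the genotype and the replicate number, and the treatment of each table is known only from the names of the workbook and its sheet. Groups were taken from the sample titles.

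Of the symbols, 23961 matched a GENCODE gene name and 297 a RefSeq symbol on GRCm38, 225 matched none and 43 matched several genes. A further 26 symbols had been turned into dates by a spreadsheet; they stayed in the totals and tests and are never named. Positions, biotypes and overlaps of exons on the opposite strand come from that annotation. Counts of a gene whose exons overlap those of another gene on the opposite strand depend on whether the counting used strand, and such genes are marked where named.

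Totals were 26296022 to 34561858 counts per vehicle library and 44471072 to 60016684 per cytokine library. A count of 0 in 1 library allows a level of up to 3 counts, which is 0.0868 to 0.114 CPM in the vehicle and 0.05 to 0.0675 CPM in the cytokine libraries. Floors over a group use 3 counts over its 3 libraries, and a fold against a group without counts is a lower bound against that floor. Intervals of pooled levels are exact Poisson intervals at 95%. Replicates were checked for libraries deposited more than once: every pair within a group differed beyond sampling noise, with a chi-square per degree of freedom of 24.8 to 450.5.

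Genotypes were compared within each treatment on the 6 libraries of 1 table. The cytokine effect in each genotype, and the difference of these effects, were contrasts of a fit of 4 group means to all 12 libraries, with the tables joined on the symbol. Each used the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, two-sided, on TMM-scaled counts after filterByExpr with a minimum count of 10, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The common biological coefficient of variation was 0.183 with vehicle, 0.390 with cytokines and 0.313 over all 12 libraries. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists with at least 5 tested members; 30 lists covered cytokine responses, endocrine and other pancreatic cell types, stress, metabolism and proliferation. The cytokine-raised and cytokine-lowered sets are the 200 genes with the largest rise and fall among genes called for the effect averaged over genotypes. Where members of a list had no count in a group, its median is also given with these genes at their bound.

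These tests, the lists, the alternatives of the next paragraph not marked as added, and the rule for named genes were fixed before the data were examined. The rule takes Gpr31b; the 10 largest rises and the 10 largest falls among called genes with a mean of at least 5 CPM in the higher group and no overlap between groups; up to 4 members with the smallest adjusted p of each called list; the panel Ins1, Ins2, Gcg, Sst, Nos2, Cxcl10 and Alox15; and, where fewer than 5 genes were called, the 5 genes with the smallest unadjusted p in each direction. Gene models without a proper symbol and pseudogenes were skipped, and some genes that the rule takes are not reported here. Xist, the Y-linked genes, Malat1 and the acinar share, as well as marker genes named only in the closing section, were chosen for naming after their values were seen, apart from Eif2s3y and Uty, which the rule also takes.

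Alternatives were DESeq2's size factors and upper-quartile scaling, no filter and a stricter one of at least 50 counts in 3 libraries, DESeq2 1.42.0, limma voom, the replicate number as a block, each library left out in turn, and all 12 or only the 6 libraries of a comparison; for lists, an estimated correlation, fry, and 100 or 500 genes in the cytokine sets. Added after the data were seen were the block without knockout cytokine replicate 2 or without both cytokine replicates 2, the block within treatment, only genes without opposite-strand exons, and other scalings or left-out libraries for Gpr31b. Whether the numbers pair libraries was checked by the correlation of same-numbered libraries' deviations from their group means in log2 CPM (prior count 2), with pairing taken where every pair lies over 0.1. In the cytokine table the genotypes' pairs gave 0.13, 0.34 and 0.57, and the sex markers of same-numbered libraries match, so these libraries were taken as paired; the source of that pairing is the data, since the labels state none. The vehicle table gave 0.09, -0.03 and 0.56, and numbers across tables gave -0.43 to 0.03, so these were not.

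All fits were tested on simulated data drawn from the real mean of each gene, with 200 genes changed. Means were taken over the libraries of a comparison, and for the difference of the effects over those of each treatment. For the cytokine effect this removed the treatment difference, so its figures do not cover data in which most genes change. edgeR recovered 71% of 2-fold and 93% of 4-fold changes with vehicle (12 false calls of 189; 14244 genes), 11% and 58% with cytokines (4 of 73; 14605 genes), 40% and 73% for the cytokine effect in wild type (7 of 120; 15229 genes), 41% and 73% in knockout (7 of 124; 15251 genes), and 11% and 54% for the difference of the effects (1 of 66; 15259 genes). DESeq2 made 29 false calls of 219 with vehicle and 55 of 173 with cytokines. A list shifted in the simulation was called in each comparison and no other list was. Genes were drawn independently of each other there, so this does not show how often camera calls lists of correlated genes falsely.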

Results

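Islets of Langerhans, the endocrine clusters of the pancreas that hold the insulin-producing beta cells, were compared between mice lacking Gpr31b and wild-type mice. Gpr31b encodes GPR31, a G protein-coupled receptor described as a receptor for 12-HETE, a lipid that 12-lipoxygenase makes from arachidonic acid. The islets had been cultured for 24 h with vehicle or with a mixture of the proinflammatory cytokines TNF-α, IFN-γ and IL-1β, a common model of the inflammation that beta cells meet in autoimmune diabetes. Polyadenylated RNA was sequenced as 12 strand-specific libraries in 4 groups of 3: wild type with vehicle, knockout with vehicle, wild type with cytokines and knockout with cytokines. The deposited values were counts per gene for 24552 gene symbols. The 6 vehicle libraries held 26296022 to 34561858 counts and 15795 to 16736 genes with at least 1 count, and the 6 cytokine libraries held 44471072 to 60016684 counts and 16637 to 16983 genes. Levels are given in CPM, counts scaled to the total of each library, as mean ± SD over the 3 libraries of a group. Nothing in the labels says that the libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may be technical in part. Confidence intervals of levels and floors for counts of 0 cover counting error only.

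The vehicle and cytokine libraries came in separate tables and differed in more than the treatment. Xist, which is transcribed from the inactive X chromosome in females, stood at 17.0 to 28.2 CPM in the vehicle libraries, with no count of the Y-linked genes Uty, Eif2s3y and Kdm5d. In the cytokine libraries numbered 1 and 3 of both genotypes, Uty stood at 17.3 to 22.5 CPM and Xist at 0.0208 to 0.323 CPM. In the cytokine libraries numbered 2, Xist stood at 265 CPM in wild type and 314 CPM in knockout, with Uty at 0.585 and 0.396 CPM, so within a cytokine group the library numbered 2 came from other animals than those numbered 1 and 3. The nuclear RNA Malat1 stood at 25.1 to 33.2 CPM in the vehicle libraries and at 168 to 363 CPM in the cytokine libraries. The insulin genes Ins1 and Ins2 together took 19.6 to 27.9% of the counts with vehicle and 6.39 to 12.9% with cytokines. The list of acinar genes, which report exocrine tissue carried along in the isolation, took 0.0615 to 1.59% of the counts with vehicle and 0.0847 to 2.54% with cytokines. Since no table held libraries of both treatments, treatment and table cannot be told apart in the cytokine effect, whereas genotypes were compared within a table. The cytokine libraries numbered 2, female as those with vehicle, held Nos2 at 1128 and 619 CPM against at most 0.982 CPM with vehicle, and Slc2a2 at 22.4 and 19.2 CPM against at least 597 CPM.

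The targeted gene was looked at first in every library. Gpr31b (ENSMUSG00000071311.2) is a protein-coding gene with 1 exon of 1283 bp on the minus strand of chromosome 17, from 13051014 to 13052296 in GRCm38. It was counted only in wild-type islets with cytokines, where the 3 libraries held 14, 6 and 8 counts, a mean of 0.197 ± 0.0834 CPM (n = 3). The pooled level of these libraries was 0.198 CPM (95% confidence interval 0.132 to 0.287, exact Poisson). The 3 knockout libraries with cytokines held 0 counts, which allows up to 0.0184 CPM over the group, so Gpr31b was at least 10.8-fold lower there. With vehicle, Gpr31b had 0 counts in all 6 libraries, which allows up to 0.0323 CPM in wild type and 0.0292 CPM in knockout. Its level in wild type was thus at least 6.13-fold higher with cytokines than with vehicle. Both folds, 10.8 and 6.13, set the pooled level against a floor. They leave out the counting error of that level, whose interval starts at 0.132 CPM, so the true folds may be smaller. Between genotypes no difference was detectable with vehicle at this depth. Gpr31b lay below the filter on low counts and was not tested. The levels of the cytokine libraries follow the genotype labels, and the vehicle libraries hold no count that could check theirs.

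**Figure D1:**
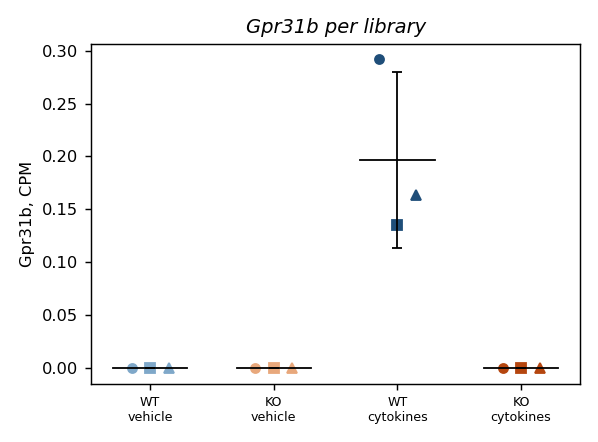
Gpr31b in each of the 12 libraries, in CPM (vertical axis) by group (horizontal axis), with the group mean ± SD as a bar. The wild-type libraries with cytokines hold 14, 6 and 8 counts, and the other 9 libraries lie at 0.

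With cytokines, interferon and NF-κB target genes were higher and beta cell genes lower in islets of both genotypes. Nos2, the inducible nitric oxide synthase (chromosome 11, 78920787 to 78960254), rose from 0.378 ± 0.529 to 1274 ± 170.1 CPM in wild type and from 0.204 ± 0.0269 to 1011 ± 349 CPM in knockout, with n = 3 per group throughout. Slc2a2, the glucose transporter of the beta cell (chromosome 3, 28697903 to 28731359), fell from 657 ± 52.8 to 18.8 ± 3.92 CPM in wild type, 36.4-fold, and from 654 ± 32.2 to 19.5 ± 1.04 CPM in knockout, 35.8-fold. By edgeR with a Benjamini-Hochberg adjusted p below 0.05, 8378 of 15420 genes (54.3%) differed between cytokines and vehicle in wild type, 4203 higher and 4175 lower. In knockout 9122 genes (59.2%) differed, 4846 higher and 4276 lower. Of the genes called higher, 3806 were called in both genotypes, where independent lists would share 1321, and of those called lower 3710 were called in both, where independent lists would share 1158. In 2 genes the calls had opposite signs. Across the 15420 genes, which are not independent replicates, the log2 fold changes of the genotypes had a Pearson correlation of 0.909 and a Spearman correlation of 0.904. The 2 comparisons contrast different libraries, but both come from 1 fit to all 12, with a common filter, scaling and estimate of spread. Leaving out knockout cytokine replicate 2 changed the calls in wild type from 8378 to 9153. Each comparison also sets the same pair of tables against each other.

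**Figure D2:**
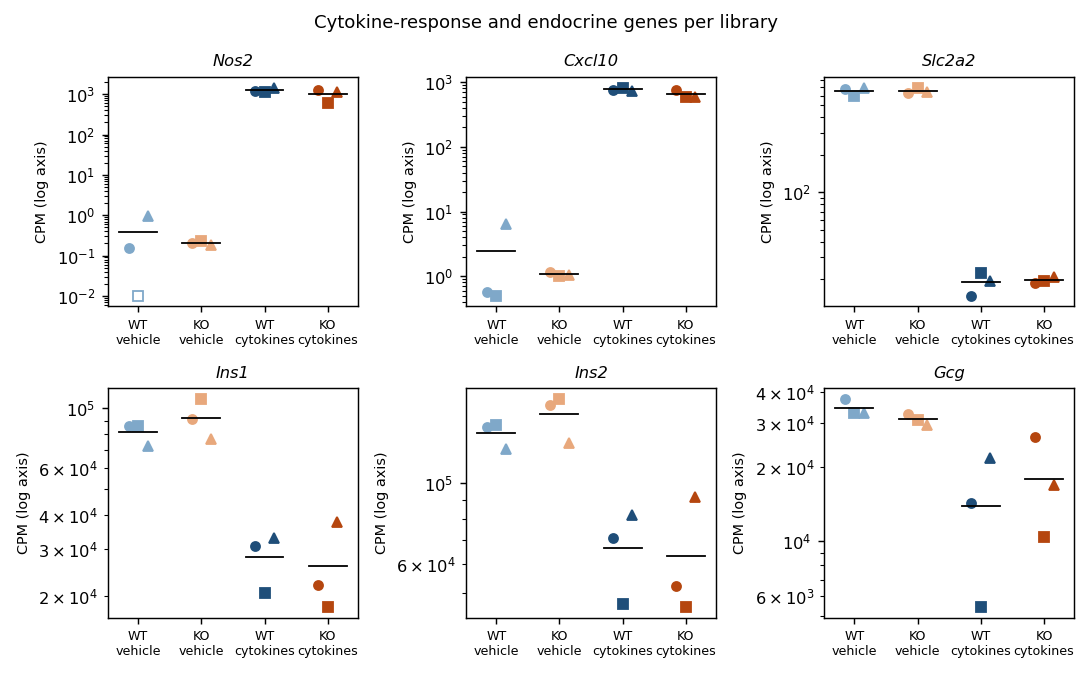
Levels of cytokine-response and endocrine genes, in CPM on a log axis (vertical), by group (horizontal), with circle, square and triangle for replicates 1, 2 and 3 and a line at the group mean; the Nos2 value of wild-type vehicle replicate 2 is 0 and is drawn open at 0.01. Cxcl10 lies at 738 to 827 CPM in wild type and 598 to 757 CPM in knockout with cytokines, and Slc2a2 falls from 597 to 696 CPM to 14.6 to 22.4 CPM.

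All 30 measured genes of the IFN-γ response list rose in both genotypes, with a median log2 fold change of 7.49 in wild type and 7.42 in knockout (camera adjusted p = 7.88e-61 and 7.17e-58). Igtp, an immunity-related GTPase, rose 83.0-fold in wild type (log2 6.37 ± 0.18 SE) and 77.8-fold in knockout (6.28 ± 0.17 SE). Cxcl9, a chemokine that draws T cells, stood at 0.0304 ± 0.0526 CPM (3 counts) in wild-type vehicle islets and at 924 ± 176 CPM with cytokines. In knockout it rose from 0.147 ± 0.0606 to 1038 ± 130.2 CPM. Gbp10, a guanylate-binding protein, rose from 0.0929 ± 0.0475 to 1369 ± 251 CPM in wild type and from 0.127 ± 0.0909 to 1212 ± 426 CPM in knockout. Serpina3g and Ido1, the latter an enzyme of tryptophan breakdown, had no count in wild-type vehicle islets and rose at least 1142-fold and at least 511-fold. All 26 type I interferon-stimulated genes rose, with medians of 4.75 and 4.71 (camera adjusted p = 6.63e-34 and 1.04e-30). Among them Zbp1, a sensor of viral nucleic acids, rose 242-fold in wild type and 354-fold in knockout, and Stat2 rose 10.005-fold and 9.10-fold. Both lists held with an estimated correlation (adjusted p = 1.5e-05 and 0.0138 in wild type, 0.000149 and 0.0146 in knockout).

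All 30 NF-κB targets rose in both genotypes, with medians of 4.16 and 4.40 (camera adjusted p = 1.32e-28 and 8.50e-26; 0.00195 and 0.00473 with an estimated correlation). Nfkbia, the inhibitor that NF-κB induces against itself, rose 25.2-fold in wild type (log2 4.65 ± 0.24 SE) and 18.0-fold in knockout (4.17 ± 0.23 SE). Birc3, a regulator of TNF signalling, rose 18.1-fold and 14.3-fold. Of 19 measured chemokines 15 rose in each genotype, and their medians with undetected genes set at their bound were 4.41 in wild type and 7.23 in knockout (5.06 and 9.14 as fitted; camera adjusted p = 3.99e-11 and 1.06e-11; 0.0104 and 0.00697 with an estimated correlation). Cxcl1, which draws neutrophils, rose from 0.296 ± 0.131 to 284 ± 106 CPM in wild type and from 0.265 ± 0.196 to 264 ± 83.8 CPM in knockout. Cxcl10, whose exons overlap those of a gene on the opposite strand, rose from 2.49 ± 3.39 to 774 ± 46.9 CPM and from 1.07 ± 0.0753 to 652 ± 91.0 CPM by edgeR (adjusted p = 8.5e-06 and 5.09e-06); DESeq2 gave log2 fold changes of 8.28 and 9.12 for Cxcl10 but no p.

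Antigen presentation rose. Of 21 MHC class I genes 18 rose in each genotype, with medians of 3.26 and 3.24 (camera adjusted p = 1.45e-27 and 2.94e-24; 0.0118 and 0.0146 with an estimated correlation). The peptide transporter Tap1 rose 41.8-fold and 36.3-fold, and the class I transactivator Nlrc5 rose 94.0-fold and 119-fold; both overlap opposite-strand exons. Of 12 MHC class II genes 9 rose in wild type and 12 in knockout, with medians of 2.97 (2.72 with genes at their bound) and 4.02. The camera adjusted p for class II was 1.09e-05 and 3.26e-06 (adjusted p = 0.226 and 0.215 with an estimated correlation). Cd74, the invariant chain, rose 11.8-fold and 12.2-fold, and the costimulatory receptor Cd40 rose 141-fold and 182-fold.

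Endocrine markers fell. In the list of beta cell identity and insulin secretion, 27 of 38 measured genes fell and 2 rose in wild type, and 30 fell and 2 rose in knockout, with medians of -1.18 and -1.40 (camera adjusted p = 2.64e-09 and 1.06e-11; adjusted p = 0.344 and 0.215 with an estimated correlation). Ero1lb, an oxidase of the endoplasmic reticulum in which proinsulin folds, fell 9.02-fold in wild type (log2 -3.17 ± 0.21 SE) and 9.60-fold in knockout (-3.26 ± 0.21 SE). Ffar1, the free fatty acid receptor that augments insulin release, fell 10.04-fold and 11.98-fold, and the transcription factor Neurod1, whose exons overlap opposite-strand exons, fell 4.75-fold and 4.90-fold. Ins1 fell 2.97-fold and 3.70-fold by edgeR (adjusted p = 0.0042 and 0.0013). Ins2 fell 2.11-fold and 2.54-fold (adjusted p = 0.0314 and 0.0101). The wild-type call of Ins2 was lost without vehicle replicate 1 (0.0889) or 2 (0.0867) or cytokine replicate 1 (0.0644) or 2 (0.0967) of wild type, with no filter on counts (0.0532) and with the replicate number as a block (0.0705). The knockout call was lost with only the 6 knockout libraries (0.051). Of 12 alpha cell markers 7 fell in wild type and 8 in knockout, with medians of -1.51 and -1.43 (camera adjusted p = 0.000616 and 0.00101; adjusted p = 0.249 and 0.245 with an estimated correlation). Gcg, which encodes glucagon, fell 2.51-fold in wild type by edgeR (adjusted p = 0.0336); without vehicle replicate 1 or 2 or cytokine replicate 1 or 2 of wild type that adjusted p was 0.0886, 0.0675, 0.0801 and 0.0584. In knockout Gcg had a log2 fold change of -0.90 ± 0.47 SE and did not pass (adjusted p = 0.122), except without wild-type cytokine replicate 2 (0.0319) or by DESeq2 (0.0437). Of 9 delta and PP cell markers 8 fell in wild type and 7 in knockout, with medians of -1.97 and -2.12 (camera adjusted p = 0.0016 and 0.00151; adjusted p = 0.18 and 0.185 with an estimated correlation). Sst, which encodes somatostatin, fell 4.65-fold and 5.45-fold.

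Lists of cell death, cytokine receptors, glycolysis and hypoxia, and antioxidant genes rose beside the immune ones. Of 31 genes of apoptosis and cell death 23 rose in wild type and 26 in knockout, with medians of 1.33 and 1.51 (camera adjusted p = 2.46e-10 and 3.41e-11). Mlkl, the executioner of necroptosis, rose 54.6-fold in wild type and 58.1-fold in knockout. Of 33 cytokine receptors and signal regulators 22 rose in wild type and 23 in knockout, and 2 fell in each, with medians of 1.4998 and 1.30 (6e-08 and 7.86e-08). Of 25 genes of glycolysis and the hypoxia response 21 rose and 1 fell in each genotype, with medians of 1.61 and 1.52 (6.05e-12 and 9.35e-11), among them Pfkfb3, which makes an activator of glycolysis, 22.7-fold and 23.5-fold higher. These 3 lists held with an estimated correlation (adjusted p = 0.00855, 0.00743 and 0.0104 in wild type and 0.00697 for each in knockout). Of 25 antioxidant genes 19 rose in each genotype, with medians of 1.08 and 1.34 (1.3e-05 and 1.55e-05; adjusted p = 0.0615 and 0.0735 with an estimated correlation). Hmox1, the haem oxygenase, rose 16.9-fold and 17.6-fold, and Sod2, the mitochondrial superoxide dismutase, 6.40-fold and 5.77-fold. Of 23 immediate early genes 12 rose in wild type and 13 in knockout (medians 1.39 and 1.57; 9.78e-05 and 6.39e-05; adjusted p = 0.358 and 0.299 with an estimated correlation; in wild type 0.73 without cytokine replicate 2), of 36 ribosomal protein genes 30 and 33 rose (0.80 and 0.96; 9.4e-05 and 2.2e-05; 0.672 and 0.62), and of 26 matrix genes 14 and 16 rose (0.84 and 1.11; 0.00603 and 0.000942; 0.609 and 0.48).

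**Figure D3:**
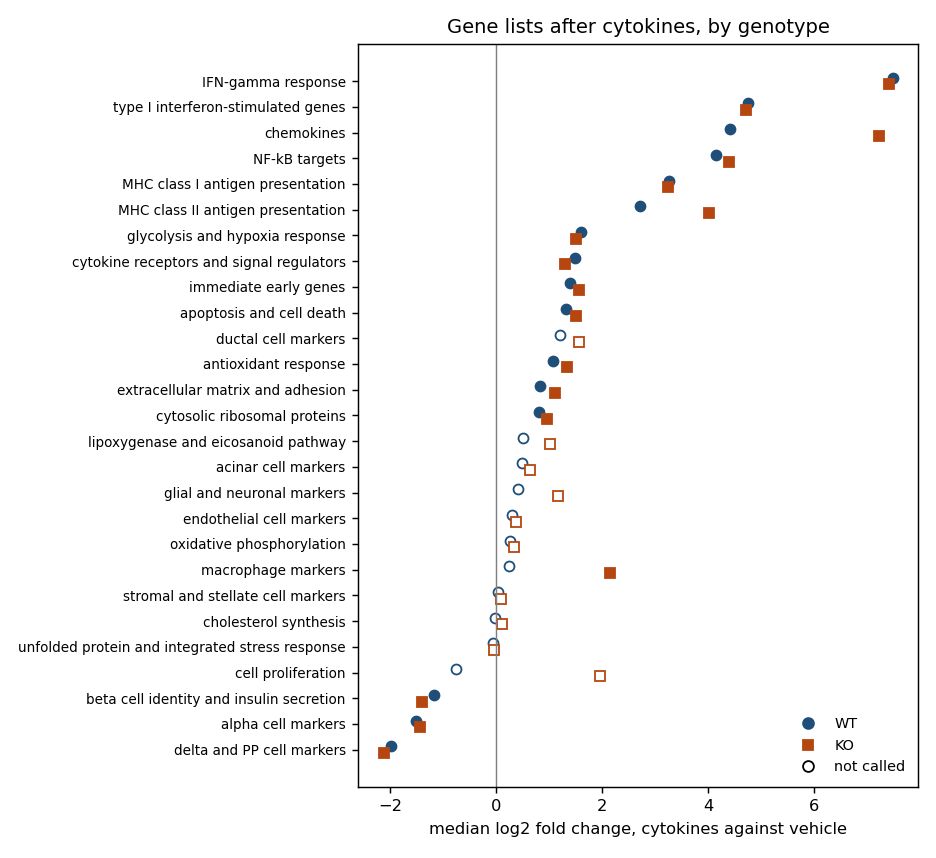
Median log2 fold change of cytokines against vehicle (horizontal axis) for each gene list tested (vertical axis), in wild type and in knockout, with undetected genes set at their bound; open points are lists that camera did not call. The IFN-γ response lies highest, at 7.49 in wild type and 7.42 in knockout, and the delta and PP cell markers lowest, at -1.97 and -2.12.

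Markers of most other cell types did not pass as lists. Macrophage markers had a median log2 fold change of 0.25 in wild type, with 3 of 20 higher and 1 lower (camera adjusted p = 0.709), and rose in knockout with a median of 2.15 and 15 of 20 higher (0.0337; adjusted p = 0.751 with an estimated correlation). That call was lost without knockout vehicle replicate 3 (0.0556) or knockout cytokine replicate 2 (median 0.81; 0.0887). Ductal markers had medians of 1.21 and 1.56 (0.161 and 0.147), endothelial markers 0.31 and 0.38 (0.709 and 0.889), and cell proliferation -0.76 and 1.97 (0.343 and 0.448; 0.0488 in knockout without cytokine replicate 3). Acinar markers had medians of 0.49 and 0.64 while their test pointed down (0.796 and 0.914). Stromal markers had medians of 0.05 and 0.10 and glial and neuronal markers 0.41 and 1.17, and in wild type the test of both pointed down (0.796 and 0.957). The unfolded protein and integrated stress response had 9 genes higher and 9 lower in wild type and 7 higher and 10 lower in knockout (medians -0.06 and -0.04, means 0.18 and 0.15; 0.903 and 0.984). Lipoxygenase and eicosanoid genes had medians of 0.51 and 1.02 (0.249 and 0.0893; 0.0264 in knockout without cytokine replicate 3), oxidative phosphorylation 0.27 and 0.34 (0.275 and 0.288) and cholesterol synthesis -0.01 and 0.11 (0.903 and 0.778). Alox15, the mouse gene of leukocyte-type 12/15-lipoxygenase, was at most 0.207 CPM as a group mean and was not tested.

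The largest falls mark a limit of this comparison. Peg3os, an antisense transcript, had no count in any cytokine library and was at least 11501-fold lower in wild type and at least 11252-fold lower in knockout, and 8 of the 10 largest falls in wild type (Slc5a2, Msmp, Zfhx2os, Mir6340, Bricd5, Zim3, Pcsk2os2 and Sla2) overlap exons on the opposite strand. Among 142 antisense genes with at least 10% of their exon bases inside coding exons of another gene the median log2 fold change, averaged over the genotypes, was -4.06. It was -1.07 for 45 antisense genes without any such overlap. Antisense genes with a smaller overlap, Pcsk2os2 among them, were in neither set. Over the 10361 genes with no opposite-strand exon overlap, edgeR called 5437 in wild type (2842 higher) and 6050 in knockout (3316 higher). The Y-linked genes Eif2s3y and Uty were among the largest rises in wild type, at least 1340-fold and at least 383-fold, beside the sex markers that differed between the tables. These folds rest on wild-type cytokine replicates 1 and 3, with Eif2s3y at 63.6 and 61.8 CPM against 1.19 CPM in replicate 2, and limma voom called neither gene (Eif2s3y adjusted p = 0.44, Uty 0.319).

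With vehicle, no single gene passed the edgeR test over all genes between knockout and wild-type islets, and 9 of 27 lists passed by camera with its preset correlation, but 0 with an estimated correlation and 0 by fry. Ngfr, a neurotrophin receptor of glia and nerve (chromosome 11, 95568818 to 95587735), stood at 19.4 ± 10.9 CPM in wild type and 5.82 ± 1.78 CPM in knockout (n = 3 each), a log2 fold change of -1.66 ± 0.35 SE. The list of glial and neuronal markers was lower by a median log2 fold change of -1.18, with 8 of 10 members negative (camera adjusted p = 2.72e-09; adjusted p = 0.541 with an estimated correlation). Extracellular matrix genes were lower by -0.37, with 25 of 26 negative (1.41e-10), stromal markers by -0.43, with 15 of 16 negative (1.89e-07), and proliferation genes by -0.46, with 24 of 24 negative (1.89e-07); with an estimated correlation these 3 had an adjusted p = 0.789. Without wild-type vehicle replicate 1 the medians of matrix and proliferation genes were -0.61 and -0.70, without replicate 3 -0.20 and -0.22, and that of stromal markers was -0.19 without replicate 2. Adjusted over the list alone, 5 glial and neuronal genes and 1 stromal gene were lower, and no member of another list passed.

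Examples from these lists were Lama4, a laminin chain of vessel walls (-0.60 ± 0.19 SE), Thy1 (-1.20 ± 0.29 SE) and the matricellular protein genes Sparc (-0.52 ± 0.20 SE) and Postn (-1.13 ± 0.44 SE). Top2a, a topoisomerase of dividing cells, was at 6.39 ± 2.65 CPM in wild type and 3.28 ± 0.908 CPM in knockout. Endothelial markers were lower by a median of -0.21, with 12 of 14 negative (camera adjusted p = 0.000465; adjusted p = 0.841 with an estimated correlation), among them Kdr, a VEGF receptor (-0.33 ± 0.11 SE). That call was lost without wild-type vehicle replicate 2 (median -0.10; 0.0759), and the median was -0.35 without knockout replicate 1 and -0.14 without knockout replicate 2.

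Another 4 lists had small shifts upwards in knockout islets with vehicle. Oxidative phosphorylation genes were higher by a median log2 fold change of 0.09 (34 of 40 positive; camera adjusted p = 0.000325), beta cell genes by 0.09 (27 of 38; 0.000465), ribosomal protein genes by 0.08 (33 of 36; 0.00241) and MHC class I genes by 0.12 (16 of 20; 0.00414); each had an adjusted p = 0.841 with an estimated correlation. Mafa, a transcription factor of mature beta cells, stood at 163 ± 80.4 CPM in knockout and 80.5 ± 23.4 CPM in wild type (log2 1.05 ± 0.31 SE), and Kcnj11, the potassium channel of insulin release, had a log2 fold change of 0.29 ± 0.09 SE. Without wild-type vehicle replicate 3 the calls of MHC class I (0.0626), oxidative phosphorylation (0.133) and ribosomal genes (0.35) were lost, and likewise without knockout vehicle replicate 2 (0.204, 0.181 and 0.825). Leaving out 1 library gave medians of 0.02 to 0.15 for oxidative phosphorylation and -0.01 to 0.18 for ribosomal genes, lowest without knockout replicate 2 and highest without knockout replicate 3; without wild-type replicate 3 they were 0.04 and 0.03. Without wild-type replicate 1 beta cell genes had 0.17 and MHC class I 0.20. Ins1 and Ins2 each had a log2 fold change of 0.25 (95% intervals -0.13 to 0.64 and -0.10 to 0.59), and Gcg and Sst had -0.09 and 0.13.

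By edgeR, 0 of 14389 genes differed between genotypes with vehicle, with a smallest adjusted p of 0.262. At an unadjusted p under 0.05 there were 973 genes, 403 higher and 570 lower in knockout, where chance gives 719 for independent genes. Other splits of the same 6 libraries, which do not follow genotype, gave 101 to 2421 such genes, so 973 is no sign of a genotype effect. DESeq2 called 30 genes, 3 higher and 27 lower, and limma voom called 0. The genes with the smallest unadjusted p, none of them called by edgeR, were lower for Hpcal4, a neuronal calcium sensor (-3.55 ± 0.43 SE), Htr3a, a serotonin-gated channel of neurons (-2.80 ± 0.35 SE), Chrna3, a nicotinic receptor subunit of ganglia (-1.93 ± 0.31 SE), Btc (-1.28 ± 0.22 SE) and Nell2 (-1.92 ± 0.34 SE). Higher were the histone genes Hist1h2bc (0.40 ± 0.08 SE) and Hist1h4i (0.97 ± 0.21 SE), Rpl13 (0.54 ± 0.12 SE), Cdh22 (0.45 ± 0.10 SE) and Tmem151b (0.47 ± 0.11 SE), the last overlapping opposite-strand exons. DESeq2 called 7 of these 10, leaving out Hist1h4i, Cdh22 and Tmem151b. Its SE for Hpcal4 was 0.659, wider than the 0.43 worked back from the edgeR test.

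The other lists did not pass with vehicle. The IFN-γ response had a median of -0.08 (camera adjusted p = 0.237), type I interferon-stimulated genes -0.08 (0.414), chemokines -0.35 (0.551), MHC class II 0.04 (0.237), alpha cell markers -0.03 (0.947), delta and PP cell markers 0.08 (0.735), acinar -0.12 (0.414) and ductal markers -0.09 (0.634). NF-κB targets had a median of 0.11 and a mean of -0.01 with a test pointing up (0.298), and macrophage markers 0.10 and -0.03, also pointing up (0.567). Antioxidant genes had a median of -0.01 and a test pointing up (0.735), and cytokine receptors a median of 0.01 and a mean of -0.02 (0.838). Lipoxygenase genes had -0.09 (0.237), apoptosis -0.06 (0.237), cholesterol synthesis -0.07 (0.104), glycolysis 0.04 (0.453), immediate early genes -0.06 (0.453) and the unfolded protein response 0.01 (0.757). The calls of these lists moved when single libraries were left out, and 7 lists were called without wild-type vehicle replicate 3 and 15 without knockout vehicle replicate 3.

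After cytokines, no gene passed between knockout and wild-type islets, and 10 of 28 lists passed by camera with its preset correlation, but 0 with an estimated correlation and 0 by fry. Nos2 had a log2 fold change of -0.30 between knockout and wild type (95% interval -1.08 to 0.47), Cxcl10 of -0.22 (-0.61 to 0.16), Ins1 of -0.06 (-1.09 to 0.97) and Ins2 of -0.02 (-1.12 to 1.08), with n = 3 per group. These intervals come from the fit without the replicate block and so ignore the pairing of same-numbered cytokine libraries. The common biological coefficient of variation was 0.390 in that fit and 0.276 with the block. Glial and neuronal markers were lower in knockout by a median of -0.85, with 10 of 10 negative (camera adjusted p = 3.02e-08; adjusted p = 0.666 with an estimated correlation), among them Ngfr at 60.1 ± 10.1 CPM in wild type and 28.4 ± 14.8 CPM in knockout. Macrophage markers were higher by 1.74, with 20 of 20 positive (4.84e-20), MHC class II genes by 0.76, with 12 of 12 positive (5.45e-07), lymphocyte markers by 4.17, with 5 of 5 positive (6.51e-06), and proliferation genes by 2.24, with 23 of 24 positive (6.08e-12). With an estimated correlation each of these 4 had an adjusted p = 0.666. Without knockout cytokine replicate 2 these medians were 0.45, 0.06, 0.83 and 0.29, and that of glial and neuronal markers -0.44; without knockout replicate 3 the latter was -1.39. Adjusted over the list alone, 4 lymphocyte genes were higher and no member of another list passed.

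**Figure D4:**
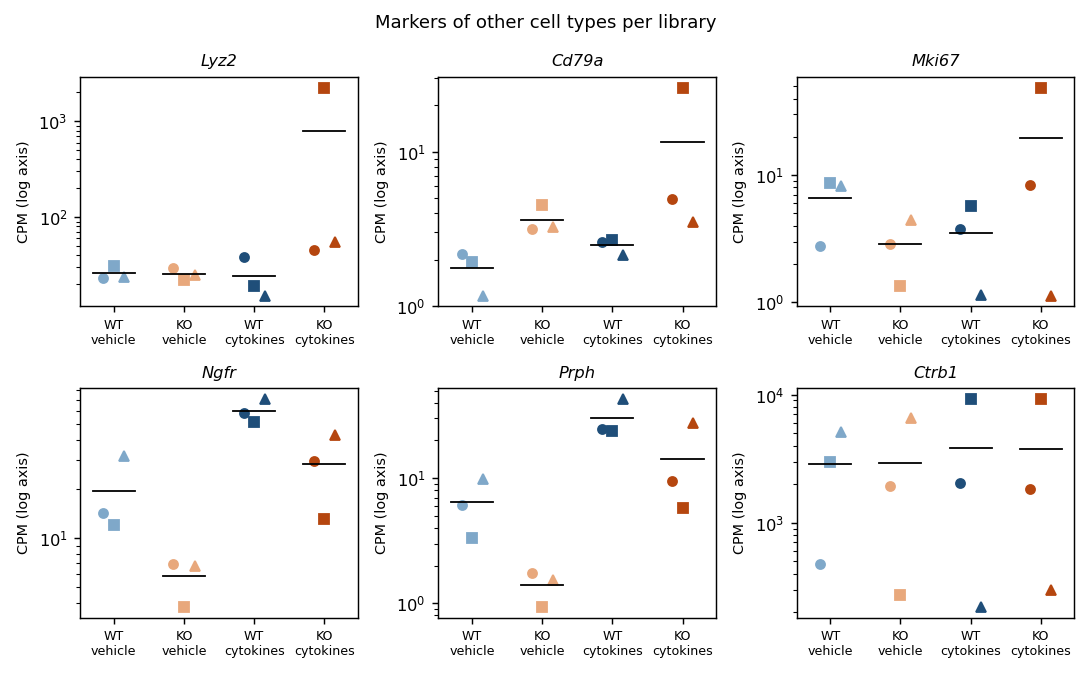
Levels of marker genes in the 12 libraries, in CPM on a log axis (vertical) by group (horizontal), with circle, square and triangle for replicates 1, 2 and 3 and a line at the group mean. Lyz2 reaches 2249 CPM in knockout cytokine replicate 2, and Ngfr lies at 12.02 to 31.9 CPM in wild type and 3.77 to 6.92 CPM in knockout with vehicle.

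The size of the immune and proliferation differences came largely from 1 library. In knockout cytokine replicate 2, Lyz2, the lysozyme of macrophages, stood at 2249 CPM against at most 55.4 CPM in every other library, and Cd79a, part of the B cell receptor, at 26.1 CPM against at most 4.93 CPM. Of 37 macrophage, lymphocyte and MHC class II markers, 33 were highest of the 6 cytokine libraries in this one. Without it, macrophage markers were higher by a median of 0.45 (camera adjusted p = 4.47e-11) and lymphocyte markers by 0.83 (0.00357), while MHC class II had 0.06 (0.21) and proliferation 0.29 (0.191). Glial and neuronal markers were lower without it too, by -0.44 (3.57e-05). With an estimated correlation the adjusted p without this library was 0.803 for macrophage and lymphocyte markers and 0.924 for glial and neuronal markers.

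The remaining shifts after cytokines were small. Ribosomal protein genes were higher in knockout by 0.26 (35 of 36 positive; camera adjusted p = 2.67e-06; adjusted p = 0.951 with an estimated correlation) and oxidative phosphorylation genes by 0.15 (39 of 40 positive; 0.00718; adjusted p = 0.993 with an estimated correlation). Type I interferon-stimulated genes were lower by -0.15, with 25 of 26 negative (0.000337; adjusted p = 0.803 with an estimated correlation), for example Oasl2 (-0.27 ± 0.18 SE), Ifit2 (-0.32 ± 0.22 SE) and Oas2 (-0.31 ± 0.23 SE), all 3 antiviral proteins. Endothelial markers were lower by -0.24, with 15 of 15 negative (0.000337; adjusted p = 0.803 with an estimated correlation), and beta cell genes by -0.10, with 30 of 38 negative (0.0045; adjusted p = 0.993 with an estimated correlation), among them Glp1r, the receptor of the incretin GLP-1 (-0.25 ± 0.26 SE). Without knockout cytokine replicate 2, type I interferon-stimulated genes had -0.06 (0.364), endothelial markers 0.00 (0.995) and beta cell genes turned to 0.10 higher (0.0239), while acinar markers were lower by -1.498 (4.82e-13). The acinar share of the counts in wild type and knockout was 0.61 and 0.476% in the libraries numbered 1, 2.30 and 2.54% in those numbered 2 and 0.0847 and 0.112% in those numbered 3, so that comparison keeps 1 of 2 libraries high in acinar genes; without both and with the number as a block acinar markers had 0.431. Beta cell genes and acinar markers without this library each had an adjusted p = 0.924 with an estimated correlation. With the number as a block as well, endothelial markers without this library turned higher in knockout and passed by camera, in a fit with 1 residual degree of freedom. Without wild-type cytokine replicate 2 the calls of endothelial (0.285), ribosomal (0.138) and oxidative phosphorylation genes (0.987, turned) were lost, without wild-type replicate 3 those of type I interferon-stimulated (0.229) and beta cell genes (0.151), and without knockout replicate 3 those of oxidative phosphorylation (0.195, turned) and ribosomal genes (0.954, turned). Their medians without wild-type replicate 2 were -0.04 (endothelial), 0.15 (ribosomal) and 0.03 (oxidative phosphorylation), and without knockout replicate 3, 0.02 (ribosomal) and -0.09 (oxidative phosphorylation). Without knockout replicate 1 the medians were -0.69 (endothelial), 0.44 (ribosomal), 0.28 (oxidative phosphorylation) and -0.17 (beta cell), and without wild-type replicate 3, 0.24 (oxidative phosphorylation), -0.08 (interferon-stimulated) and -0.05 (beta cell). Beta cell genes had -0.17 without wild-type replicate 2 and -0.23 without knockout replicate 3, and interferon-stimulated genes -0.30 without wild-type replicate 1 and -0.24 without knockout replicate 3.

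**Figure D5:**
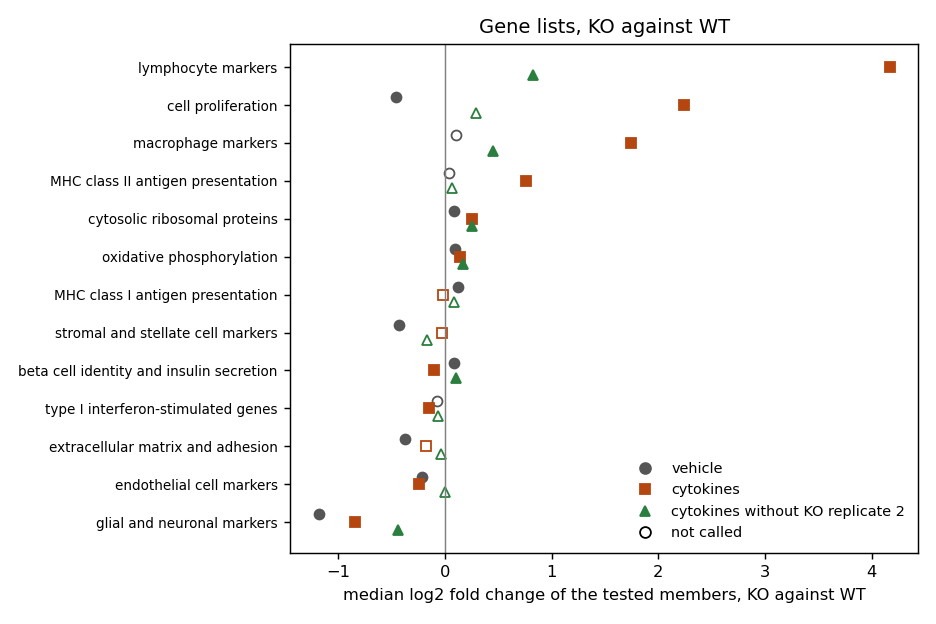
Median log2 fold change of knockout against wild type (horizontal axis) for each gene list (vertical axis) with vehicle (grey circles), with cytokines (orange squares) and with cytokines without knockout replicate 2 (green triangles). The glial and neuronal list lies at -1.18, -0.85 and -0.44, and the proliferation list at -0.46, 2.24 and 0.29.

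By edgeR, 0 of 14852 genes differed between genotypes after cytokines. At an unadjusted p under 0.05 there were 320 genes, 264 higher and 56 lower, where chance gives 743 for independent genes, and DESeq2 and limma voom each called 0. That balance changed with the method: with the replicate number as a block there were 449, 215 higher and 234 lower, by limma voom 131, 28 higher and 103 lower, and without knockout replicate 2, 82 genes, 39 higher and 43 lower. None of the genes with the smallest unadjusted p passed. Higher in knockout were Nlrc4, an inflammasome sensor (4.86 ± 1.04 SE), Dynlt1b (1.16 ± 0.30 SE), F7 (3.06 ± 0.79 SE), Stab2 (3.05 ± 0.83 SE) and Ptprcap (6.17 ± 1.70 SE), and lower were the neuronal genes Epha5 (-1.78 ± 0.44 SE), Ncan (-2.62 ± 0.70 SE), Cacna1b (-0.89 ± 0.26 SE) and Slit1 (-2.53 ± 0.73 SE), and Pla2g3 (-2.35 ± 0.64 SE); Stab2, Ptprcap and Pla2g3 overlap opposite-strand exons. Same-numbered libraries of the 2 genotypes deviated together in the cytokine table, and with the number as a block edgeR again called 0 genes, while the list of apoptosis and cell death passed (median 0.08; camera adjusted p = 0.0495 with the block and 0.0993 without). Without the block the adjusted p of that list was 0.752 with an estimated correlation and 0.995 by fry.

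The other lists did not pass after cytokines. The IFN-γ response had a median of -0.01 and a mean of 0.06 (camera adjusted p = 0.955), NF-κB targets -0.04 and 0.23 (0.955), chemokines 0.07 (0.254) and MHC class I -0.02 with a mean of 0.02 (0.974). Lipoxygenase genes had 0.15 (0.0578), matrix genes -0.18 (0.144), stromal markers -0.03 (0.878), alpha cell markers -0.05 with a mean of 0.00 (0.955), delta and PP cell markers -0.03 with a mean of 0.14 (0.955), acinar markers 0.12 (0.974) and ductal markers 0.04 with a test pointing down (0.955). The unfolded protein response had a median of 0.01 and a mean of -0.01 (0.653), antioxidant genes 0.01 (0.653), cytokine receptors 0.02 (0.534) and immediate early genes 0.08 (0.707). Glycolysis had 0.00 and cholesterol synthesis 0.02, both with a test pointing down (0.955 and 0.955). Lists of mitochondrially encoded and red blood cell genes had too few measured members to be tested in any comparison.

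Whether the response to cytokines itself differed between genotypes was tested as the difference of the effects, which cancels what both genotypes share. No gene of the inflammatory response passed: Nos2 had a difference of 0.56 on the log2 scale (95% interval -1.66 to 2.78) and Cxcl10 of 0.90 (-1.13 to 2.93), and Ins1 and Ins2 of -0.32 (-1.46 to 0.83) and -0.27 (-1.44 to 0.89). The signs for Nos2 and Cxcl10 rested on wild-type vehicle replicate 3, where Cxcl10 stood at 6.40 CPM against 0.494 to 1.16 CPM in the other vehicle libraries; without it the differences were -1.60 and -1.25, and neither was called by edgeR. For Nos2 limma voom gave -0.85. The IFN-γ response list had a median difference of 0.16 with genes at their bound and a mean of -0.05 (camera adjusted p = 0.72), type I interferon-stimulated genes -0.06 and 0.08 (0.529), and NF-κB targets -0.06 with genes at their bound and a mean of 0.27 (0.529). Chemokines had 0.90 with genes at their bound (0.0507), which passed with DESeq2's size factors (0.04), but not with an estimated correlation (adjusted p = 0.855), by fry (0.983) or with the replicate block (0.139). The genes that cytokines raised most over both genotypes (n = 200) had a median difference of 0.23 (camera p = 0.424). Those lowered most (n = 200) had -0.04 (camera p = 0.998). Only 24 of the lowered genes passed the filter on counts within the cytokine libraries. That set therefore says little about genes that fell less and stayed measurable, such as most beta cell genes. Without wild-type vehicle replicate 2 the raised genes (n = 200) had p = 0.0169 by camera. Both sets were chosen on all 12 libraries, so a gene high in a single cytokine library could enter the raised set through it. Between knockout and wild type within the cytokine libraries, the raised genes were higher by a median of 0.09 (camera p = 0.0157, and p = 0.158 with an estimated correlation). Without wild-type cytokine replicate 2 that p was 0.625, without knockout replicate 1 0.0567 and without knockout replicate 3 0.0887. The 24 lowered genes that could be tested there were lower by -0.28 (p = 0.0114; 0.0485 with an estimated correlation), and leaving out any 1 library gave 0.0963 to 0.766, with the direction turned without wild-type replicate 3 (0.753).

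By camera with its preset correlation 5 of 27 lists passed for the difference of the cytokine effect, but 0 with an estimated correlation and 0 by fry, and no gene passed by edgeR. Beta cell genes had a more negative effect in knockout, that is a larger fall, by a median of -0.22 with 31 of 38 negative (camera adjusted p = 1.42e-05). That adjusted p was 0.983 with an estimated correlation. The list was led by Foxa2 (-0.40 ± 0.18 SE) and Mafa (-1.004 ± 0.47 SE), 2 transcription factors of the beta cell. Mafa fell to 3.02 ± 0.554 CPM in wild type and 3.02 ± 0.820 CPM in knockout with cytokines, from the unequal vehicle levels above. Macrophage markers had a higher effect by 1.62, with 20 of 20 positive (2.87e-13), proliferation by 2.84, with 23 of 24 positive (1.09e-14), stromal markers by 0.36, with 14 of 16 positive (0.0164), and matrix genes by 0.26, with 22 of 26 positive (0.0122), including the metalloproteinase Mmp3 (2.16 ± 0.85 SE). With an estimated correlation the adjusted p was 0.812 for macrophage markers and proliferation and 0.983 for stromal and matrix genes. Without knockout cytokine replicate 2, the library high in immune markers, the medians of macrophage markers and proliferation shrank to 0.35 (0.000143) and 0.69 (2.09e-05), and the beta cell call was lost (-0.05; 0.46). Matrix genes had 0.000783 there. The beta cell median was -0.14 without wild-type cytokine replicate 3 and -0.39 without knockout cytokine replicate 3. The stromal call was lost without wild-type vehicle replicate 2 (0.0957) or 3 (0.0953), knockout vehicle replicate 2 (0.108), wild-type cytokine replicate 2 (0.0559) or 3 (median 0.16; 0.417) or knockout cytokine replicate 1 (0.253), and the median was 0.60 without wild-type vehicle replicate 1 and 0.79 without wild-type cytokine replicate 1. The matrix call was lost without wild-type vehicle replicate 2 (0.0775) or 3 (median 0.13; 0.277), knockout vehicle replicate 2 (0.11; 0.108), wild-type cytokine replicate 3 (0.14; 0.306) or knockout cytokine replicate 1 (0.01; 0.912), and the median was 0.49 without wild-type vehicle replicate 1 and 0.42 without knockout cytokine replicate 3.

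By edgeR, 0 of 15420 genes differed in their cytokine effect between genotypes. At an unadjusted p under 0.05 there were 540 genes, 376 with a higher (more positive) and 164 with a lower (more negative) effect in knockout. Chance gives 771 for independent genes, and DESeq2 and limma voom each called 0. By limma voom there were 258 such genes, 97 with a higher and 161 with a lower effect. With the replicate number as a block within treatment, chosen after seeing the data, there were 872, 400 higher and 472 lower, and edgeR called 0 (smallest adjusted p = 0.140, and 0.0538 without knockout cytokine replicate 2). The smallest unadjusted p, none of them called, belonged to Nlrc4 (5.79 ± 1.25 SE), F7 (3.81 ± 0.98 SE), Il7r (1.35 ± 0.35 SE), Card14 (2.79 ± 0.61 SE) and Tssk1 with a higher effect, and to Pla2g3 (-3.79 ± 0.82 SE), Prss57 (-3.14 ± 0.71 SE), Chadl (-1.72 ± 0.45 SE), Lhx3 and Ugt1a6b with a lower one. All but Nlrc4, F7 and Il7r overlap opposite-strand exons, and Tssk1 and Ugt1a6b have a group with no count. The remaining lists did not pass: MHC class I had -0.13 (camera adjusted p = 0.0893), MHC class II 0.40 (0.222), apoptosis 0.12 (0.0728), lipoxygenase genes 0.25 (0.0872), ribosomal genes 0.14 (0.201), glial and neuronal markers 0.24 (0.916; 0.0139 without knockout cytokine replicate 2), and the other 12 lists had an adjusted p of 0.529 to 0.964. In simulated data with 200 genes changed, edgeR recovered 71% of 2-fold and 93% of 4-fold changes between genotypes with vehicle, 11% and 58% after cytokines, and 11% and 54% for the difference of the effects, all in fits without the replicate block.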

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

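In this part, the tests that weigh the immune markers of 1 library were chosen only after the result was seen, while the differences of list effects and the counts over other splits of the libraries were planned.

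For 5 gene lists the difference of the cytokine effect between knockout and wild type passed by camera with its preset correlation, which is what brought them here; with an estimated correlation 0 lists passed (adjusted p = 0.812 to 0.983), and by fry 0. Relative to wild type, the median log2 effect in knockout differed by -0.22 for beta cell genes, 0.36 for stromal markers, 1.62 for macrophage markers, 2.84 for proliferation genes and 0.26 for extracellular matrix genes. Without knockout cytokine replicate 2 the medians of macrophage markers and proliferation genes were 0.35 and 0.69 and that of beta cell genes -0.05, with their call lost (camera adjusted p = 0.46), while the matrix call was lost without knockout cytokine replicate 1 (0.01; 0.912) and the stromal call without wild-type cytokine replicate 3 (0.16; 0.417). Chance was not excluded for these counts: of 100 splits of the libraries within treatments, the real one included, 100 called at least as many lists as the real 5, with a highest other value of 20. For single genes 100 of 100 splits reached the real count of 0, and the highest other split called 4.

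Immune markers were high in knockout cytokine replicate 2, and with them the macrophage, lymphocyte, MHC class II and proliferation lists. Of the 37 measured markers of macrophages, lymphocytes and MHC class II, 33 were at their highest of the 6 cytokine libraries there, by a median log2 ratio of 2.76 to the median of the other libraries. Islets with vehicle express 28 of these markers at 1 CPM or more, and 1 belongs to another list too; the most abundant in this library were Lyz2 at 2249, Cd74 at 766 and Mpeg1 at 639 CPM, with Cd79a at 26.1 and Cd3e at 6.61 CPM. A rise by the knockout itself as the whole source is not decided. Without this library the median log2 fold change of the markers between genotypes was 0.352 (95% bootstrap interval 0.22 to 0.49). That lay below the limit of 1, which was set after the result was seen. The library was left out for its high immune markers, so a smaller value was bound to follow. The interval covers the spread between genes, not between libraries. Whether lymphoid tissue carried into that preparation or something else in it raised them cannot be told apart, because these same genes singled the library out, so the 33 of 37 are no test of it.

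Other splits of the same 6 libraries were counted for each remaining comparison, and 10 splits are too few for a share under 0.05. With vehicle, 10 of 10 splits reached the real count of 0 genes, the highest other calling 132, and 7 of 10 reached the real 9 lists, the highest other calling 15. The split with 132 calls set wild-type replicate 1 and knockout replicates 1 and 2 against the rest, which points to a structure of the vehicle libraries other than genotype. It also parted them by the acinar share of the counts. That share was 0.104, 0.424 and 0.0615% in these libraries, 0.878 and 1.29% in wild-type replicates 2 and 3 and 1.59% in knockout replicate 3. Whether exocrine tissue accounts for the 132 calls was not tested. With cytokines, 10 of 10 splits reached 0 genes, the highest other also calling 0, and 9 of 10 reached the real 10 lists, the highest other calling 20. The 3 other splits that part all 3 numbered pairs of cytokine libraries called 0 genes, with 234, 146 and 393 genes at an unadjusted p under 0.05 against the real 320, and 11, 10 and 14 lists against the real 10; they exchange the genotypes within 1 pair. For cytokines against vehicle, 1 of 10 splits reached 8378 genes in wild type and 1 of 10 reached 9122 in knockout, every other split calling 0, while 9 of 10 reached the real 16 lists in wild type (highest other 21) and 8 of 10 the real 17 in knockout (highest other 24).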

How the results depend on the processing

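Here the block combined with left-out libraries, the restriction to genes without opposite-strand exon overlap, the block within treatment and the tries on Gpr31b were chosen after seeing the data, and all other alternatives were planned. The count of genes between genotypes was 0 under every alternative but the ones named here. DESeq2 called 30 genes with vehicle (3 higher, 27 lower). With cytokines, the replicate block without knockout replicate 2 gave 31 genes (19 higher, 12 lower) and 5 lists, and the replicate block without both replicates 2 gave 34 genes (20 higher, 14 lower) and 6 lists; each of these fits has 1 residual degree of freedom, and the cause was not tested. In these 2 paired fits beta cell genes turned (camera adjusted p = 0.822 and 0.797), as did endothelial markers (0.00198 and 0.00179), and the cytokine-raised genes (n = 200 and n = 199) had camera p = 0.299 and 0.327. With an estimated correlation 0 lists were called with vehicle, 0 with cytokines and 0 for the difference, and 8 in each genotype for the cytokine effect; fry called 0 lists with vehicle, 0 with cytokines and 0 for the difference. The cytokine-raised genes between genotypes had p = 0.158 with an estimated correlation, and the cytokine-lowered ones 0.506 with 100 (5 tested) and 0.126 with 500 genes per set. In the difference of effects, the lowered genes turned up with 100 genes (0.438) and with the replicate block (0.8003), and 500 raised genes gave 0.0309. The block within treatment without knockout cytokine replicate 2 called 8 lists there. The genes without opposite-strand exon overlap gave 5437 calls in wild type and 6050 in knockout, as fewer genes were tested. For every other change in this part the cause was not tested. The replicate block changed no other call of a list or comparison than apoptosis after cytokines; of the called genes that are named it ended Ins2 in wild type (0.0705). Of all called genes it lost 1025 in wild type and 1327 in knockout.

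Leaving out each library in turn gave 0 to 0 genes between genotypes with vehicle, with cytokines and for the difference, 7298 to 9153 for cytokines in wild type and 7812 to 9170 in knockout. Lists numbered 7 (without wild-type replicate 3) to 15 (without knockout replicate 3) with vehicle, 7 (without knockout replicate 2) to 13 with cytokines, 16 to 16 and 16 to 19 for the cytokine effect, and 6 to 14 (without knockout cytokine replicate 3) for the difference. Adjusted p after cytokines ran from 1.22e-05 to 0.151 for beta cell genes (turned at 0.0239), 1.36e-07 to 0.995 for endothelial (turned at 0.995), 1.17e-06 to 0.987 for oxidative phosphorylation (turned at 0.987 and 0.195) and 6.66e-14 to 0.954 for ribosomal genes (turned at 0.954). The p of cytokine-raised genes ran from 7.78e-05 to 0.625 between genotypes and from 0.0169 to 0.84 in the difference, and that of lowered genes from 0.0963 to 0.766 (turned at 0.753) and from 0.533 to 0.995. The mean of Gpr31b ran from 0.15 to 0.228 CPM.

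Calls lost over all called genes, among genes still tested, numbered 415 in wild type and 429 in knockout with upper-quartile scaling, 376 and 719 by limma voom, 331 and 353 with no filter and 150 and 1143 with only the libraries of that genotype. With a library left out they numbered 24 to 1191 and 150 to 1393, and in knockout the estimate of 7 called genes changed sign without knockout cytokine replicate 2. Of the values of the called genes that are named, under the other alternatives, 729 kept their direction and call in wild type and 6 lost the call, and 758 and 6 did in knockout, counting 2 and 1 genes to which DESeq2 gave no p; with a library left out these were 1012 and 8, and 1056 and 0. Of called lists, 18 kept and 18 lost the call with vehicle, 27 and 29 with cytokines, where 4 more turned, 72 and 8 in wild type, 75 and 10 in knockout and 14 and 11 for the difference. With a library left out these were 47 and 7, 48 and 7 (5 more turned), 192 and 0, 202 and 2, and 48 and 12. Lists not called gained a call in 13, 15, 0, 2 and 39 values with a library left out and in 0, 1, 2, 2 and 4 under the other alternatives. Upper-quartile scaling moved the median of all genes by -0.10 in wild type and -0.09 in knockout, and the share of calls that were higher from 50.2 to 44.7% and from 53.1 to 48.4%. Depth limits Gpr31b, at 28 counts in all. The spread between libraries limits mainly the genotype comparison after cytokines and the difference of the effects. In simulated data edgeR recovered 11% of 2-fold changes in each of these, against 71% with vehicle.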

Other observations

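In this part, the tests of neuronal and glial genes and of genes near Gpr31b were chosen only after the result was seen, and the tests of antisense genes were written down before.

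DESeq2 called 27 genes lower and 3 higher in knockout islets with vehicle, where edgeR called 0, with 973 genes at an unadjusted p under 0.05, and limma voom 0. Among the 27, named after their values were seen, were Nid1 (-0.74), Vim (-0.69), Btc (-1.28), Htr3a (-2.81, DESeq2 adjusted p = 1.77e-08), Prph, an intermediate filament of peripheral neurons (-2.12, 0.000114), Sncg (-1.89, 0.000177), Stmn2 (-2.23, 0.000304), and Slc5a7 and Slc18a3, the choline and acetylcholine transporters of cholinergic neurons (-2.42, 0.00451, and -2.27, 0.0321). The 3 higher genes were Rpl13 (0.54, 0.00422), Hist1h2bc (0.40, 0.0185) and Vstm2l (0.51, 0.0242). Prph stood at 3.35 to 9.76 CPM in wild type and 0.929 to 1.74 CPM in knockout with vehicle, and at 23.6 to 42.9 and 5.74 to 27.8 CPM with cytokines.

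After cytokines, a fit with the replicate number as a block and without knockout replicate 2, also chosen after seeing the data, called 12 genes lower, among them Adcyap1, which encodes the neuropeptide PACAP (-1.39), Nos1, the neuronal nitric oxide synthase (-1.45), Prph (-0.97) and Ngfr (-0.83; edgeR adjusted p = 0.0393). Of these 12, 10 went the same way in the left-out pair, 4 were among DESeq2's calls with vehicle, and 11 of 11 tested were negative with vehicle. It called 19 genes higher, with the smallest p for Cldn2, a tight junction protein (2.67), of which only 2 went the same way in the left-out pair and 15 of 15 tested were negative with vehicle. That fit has 1 residual degree of freedom.

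Glial and neuronal markers were lower in knockout with both treatments: 8 of 10 with vehicle and 10 of 10 with cytokines, by -1.01 and -1.02 in mean log2 CPM, and by -0.44 with cytokines without knockout replicate 2. Islets of wild type with vehicle express 9 of the 10 at 1 CPM or more. Whether higher islet purity in the knockout preparations lowered them is not decided. Averaged over both treatments and without knockout cytokine replicate 2, 94 markers of other non-endocrine cells had a median of -0.21. The 10 glial and neuronal ones had -0.72, a difference of 0.517 (95% bootstrap interval 0.17 to 0.99). Over the 64 that are not acinar the difference was 0.660 (0.35 to 1.12). The glial and neuronal list was picked because it was lower, and these intervals resample genes, not libraries. The gap is therefore no test of purity. Whether the lower levels come from less nerve tissue after dissection or from genotype cannot be told apart, as preparations and genotypes coincide. Exact permutations of the marker level gave p = 0.02 over 400 regroupings within treatments and p = 0.0125 over 160 that keep the cytokine pairs. The latter is the smallest possible p there. By treatment, the exact permutation p was 0.1 with vehicle, the smallest possible, and 0.2 with cytokines. Knockout cytokine replicate 3, at 2.20 in mean log2 CPM, lay above wild-type cytokine replicate 2, at 1.65. These markers had been seen to be lower, so the permutations restate the pattern and support no explanation of it.

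Of the 27 genes lower by DESeq2 with vehicle, 25 were lower in knockout with cytokines too (median log2 -0.76). Without knockout cytokine replicate 2 these values were 23 of 27 and -0.44. In 10000 random sets matched on expression, a mean of 11.7 and at most 22 genes were lower. The sets were matched on expression, not on how genes vary together between libraries. They therefore cannot decide whether 25 of 27 exceeds the spread between libraries. By camera the 27 genes had p = 1.61e-16 with the preset correlation and camera p = 0.0531 with an estimated correlation.

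Over all 13866 genes tested with both treatments, the log2 fold changes between genotypes had a Pearson correlation of -0.00338 and a Spearman correlation of -0.0126 across genes, which are not independent replicates.

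Antisense transcripts stood higher with vehicle than with cytokines. Those with at least 10% of their exon bases inside coding exons of another gene summed to 745 to 857 CPM per vehicle library. In the cytokine libraries they summed to 152 to 175 CPM. Counting without strand in the vehicle table and with strand in the cytokine table may account for part of it. The median log2 effect of the 142 genes with at least 10% overlap lay below that of 45 antisense genes without overlap by -2.99 (95% bootstrap interval -4.04 to -2.30, permutation p = 0.00021). A lowering of antisense transcripts by cytokines cannot be told apart from other differences between the tables: the genes without overlap had a median of -1.07 (interval -1.42 to -0.39), and lincRNA genes without opposite exons -0.68. Protein-coding genes had medians of 0.16 without and 0.02 with opposite-strand exons.

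Genes near the target were counted for a segment of another mouse strain. Within 10 Mb of Gpr31b, 3 of 101 genes (Pisd-ps2, Qk and Thbs2) had an unadjusted p under 0.05 with vehicle, 2.97% against 6.8% elsewhere (Fisher's exact test, one-sided, p = 0.971), and 4 of 105 (Dynlt1b, Fpr2, Tagap and Tmem181b-ps) with cytokines, 3.81% against 2.15% (p = 0.192). Such a segment is neither shown nor excluded by these few genes.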
